A study of Mus musculus with 9 samples.

How the data were processed

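Total RNA of cortical neurons from P3 mice was extracted with a Qiagen RNeasy Plus Micro kit and made into libraries with SMARTer and Nextera reagents, per the labels' protocols. The submitters' processing notes name TopHat2 2.0.11, HTSeq 0.6.1 and the mouse build mm10, without their order or settings. The annotation used for counting, whether strand was used, the scaling and the filter on genes are not given in the sources used here. The labels name no sort or gate. Samples were grouped by the plasmid and the day of electroporation in their titles, and each library has its own column, so replicates were not pooled. Reads of genes with near-identical copies, overlapping genes and antisense genes are uncertain, since the counting could split or mix them.

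The deposited values are on a log2 scale made by the authors, and were found to be a variance-stabilising transform of scaled reads. Each value equals 2/ln 2 times the inverse hyperbolic sine of the square root of a whole number of reads times a step that is constant within a library. Undoing it gave whole reads for 100% of the values in each library, with a largest distance from a whole number of 1.4e-08 and a tolerance of 1e-06. The library factors implied by the steps equal median-of-ratios factors of the recovered reads, with a largest difference of 1.15e-14. The scale is near log2 for abundant genes and near a square root below 158 to 255 reads, depending on the library, and 39.6% of genes have a mean below that. The files hold 12571 genes, each with at least 10 reads in at least 7 of the 9 libraries, so a gene silent in a whole group of 3 is not among them. Recovered totals run from 11025903 to 15772249 reads per library, and PCR copies among them are not independent molecules. No pair of libraries agreed within sampling noise: chi-square per degree of freedom was 21.24 to 38.99 among the 4 libraries with over 2% Rn45s reads, which come from all 3 groups, and 53.31 to 82.29 within the E14.5 controls.

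The design fixed before the data were examined expected counts and a count model. For a normalised unit it named limma on log2(value + 1) instead. The deposited values are already on a log2 scale, so no further log was taken, which departs from that design. Because the deposited unit is a log2 value, the main test was limma 3.58.1 (R 4.3.3) with an intensity trend on the deposited values of all 9 libraries, with 1 mean per group and 6 residual degrees of freedom, and Benjamini-Hochberg adjustment over the 12571 genes of each comparison. A gene was called at an adjusted p under 0.05. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 29 lists in 3 comparisons (87 tests), and again with an estimated correlation and with fry, which asks whether a list's genes move on balance one way. With the preset correlation 11, 17 and 16 lists passed in Kir2.1 against E14.5 control, E15.5 against E14.5 control and Kir2.1 against E15.5 control. With an estimated correlation 0 passed in each. With fry 1 passed in the first (interneuron), 2 in the second (callosal, and sodium and calcium channels) and 1 in the third (microglia and macrophage). Adjustment over a list alone used the p-values of its members only. Single genes were also compared with two-sided exact permutation tests, whose smallest p for 3 against 3 is 0.1.

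The lists were layer 4, layer 2/3, genes shared by upper-layer neurons, callosal, layer 5/6 and subplate, radial glia, intermediate progenitor, cell cycle, immature migrating neuron, interneuron, astrocyte, oligodendrocyte lineage, microglia and macrophage, endothelial and mural, immediate-early, late activity response, potassium channels, sodium and calcium channels, glutamate and GABA receptors, Wnt and beta-catenin, axon guidance, synaptic, unfolded protein and stress, p53 and apoptosis, interferon response, cholesterol synthesis, glycolysis and hypoxia, ribosomal protein and sex-linked genes. Lists for blood, meninges, choroid plexus and mitochondrial genes had 1, 2, 1 and 0 measured members, under the minimum of 3, and were not tested. The lists came from textbook markers and were fixed before the data were examined. The genes named are Kcnj2, Rorb, Cux1, Cux2 and Pou3f2, in each direction up to 8 called genes with the smallest adjusted p, a mean of at least 5 CPM and no overlap between the groups, leaving out unnamed predicted genes, pseudogenes and mitochondrial genes, and from each list up to 4 members with the smallest p in the comparison. Some genes that this rule selects are not reported here. Globin and meningeal genes come from the untested lists. Positions are those of GENCODE mouse release M21, on the same build, matched by symbol for 76 of 77 genes.

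The alternatives planned were other pseudocounts (0.1 and 5) on log2(CPM), with CPM from the recovered reads, a filter of 5 CPM in 3 libraries, a fit of 6 libraries, the replicate number as a block, and leaving out each library in turn. A pseudocount of 1, limma-voom on the recovered reads with the authors' factors or total reads, total-read scaling, quantile normalization, limma library weights, leaving out 2 doubted libraries and thinning reads to the smallest library were added after seeing the data. The library weights were computed gene by gene, because the default estimate stopped without converging.

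Unchanged groups for the relation of the first 2 comparisons were made by mixing the residuals of the fit into new libraries, 1000 times for the correlation and covariance and 100 times, with a refit, for the overlap. The procedure was tested on simulated data with 12571 independent genes. In the simulation of Kir2.1 against E14.5 control, 11.9, 46.3 and 90.9% of genes changed by 1.5-, 2- and 4-fold were recovered, with 8 false calls among 12351 unchanged genes. In that of E15.5 against E14.5 control the shares were 4.48, 38.8 and 92.4% with 5 false calls, and in that of Kir2.1 against E15.5 control 7.46, 44.8 and 92.4% with 7. The simulated libraries had no differences shared across genes, unlike the real E14.5 controls, so these shares do not carry over to the data. In Kir2.1 against E14.5 control 0 of the 12 measured microglial genes were called over all genes. Their median log2 fold of normalised reads was -3.5. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.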

Results

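RNA was sequenced from cortical neurons of mice on postnatal day 3 (P3). The neurons had received plasmids by in utero electroporation, in which a current pulse carries DNA into the progenitors lining the ventricle of the embryo, so that neurons born soon afterwards carry it. There were 3 groups of 3 libraries. The E14.5 control group received an mCherry reporter at E14.5, where E stands for the embryonic day (its replicates are numbered 2, 3 and 4), the Kir2.1 group a Kir2.1-GFP plasmid on the same day, and the E15.5 control group the reporter at E15.5, a day later. Kir2.1 is an inwardly rectifying potassium channel, the product of Kcnj2 in the mouse, and its added expression draws the membrane potential towards that of potassium. The reads behind the values numbered 11036833, 13333731 and 11025903 in E14.5 control replicates 2, 3 and 4, 15556381, 15068758 and 14348364 in Kir2.1 replicates 1, 2 and 3, and 13342675, 13657652 and 15772249 in E15.5 control replicates 1, 2 and 3. No label says that the replicates were separate animals, so the p-values measure only the spread between these libraries, which may be technical. Differences are between group means of the deposited values, on a log2 scale that flattens at low reads and so understates the change of weakly expressed genes. Folds are ratios of mean normalised reads (reads divided by the authors' library factor), and values after ± are SDs with n = 3.

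Markers of other cell types differed between libraries of the same group. The E14.5 controls were split. In replicate 3 the adult beta-globin gene (Beta-s), a red blood cell transcript, had 4409 normalised reads against 36.96 and 34.93 in E14.5 control replicates 2 and 4, and Ptgds, abundant in the meninges, had 2799 against 9.24 and 43.66. Its endothelial and mural genes averaged 4.07 against 1.28 and 1.41, and its astrocyte genes 4.96 against 4.09 and 3.78, where the other 6 libraries held 4.73 to 5.46. On the first principal component, which held 33.6% of the variance, E14.5 control replicates 2 and 4 lay at -33.52 and -31.51 and replicate 3 at 6.272. Across genes, which are not independent replicates, Pearson's r of replicate 3 was 0.955 and 0.936 with its own group and 0.972 or more with Kir2.1 replicates 1 and 3. E14.5 control replicate 2 had 127 genes at 0 reads, against 0 to 10 in the other libraries. E15.5 control replicate 1 lay farthest out on that component, at 40.7. Reads of Rn45s, the ribosomal RNA precursor, made up 2.14 to 2.44% in E14.5 control replicate 3, Kir2.1 replicates 1 and 3 and E15.5 control replicate 3, and 0.272 to 1.2% in the other 5.

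**Figure D1:**
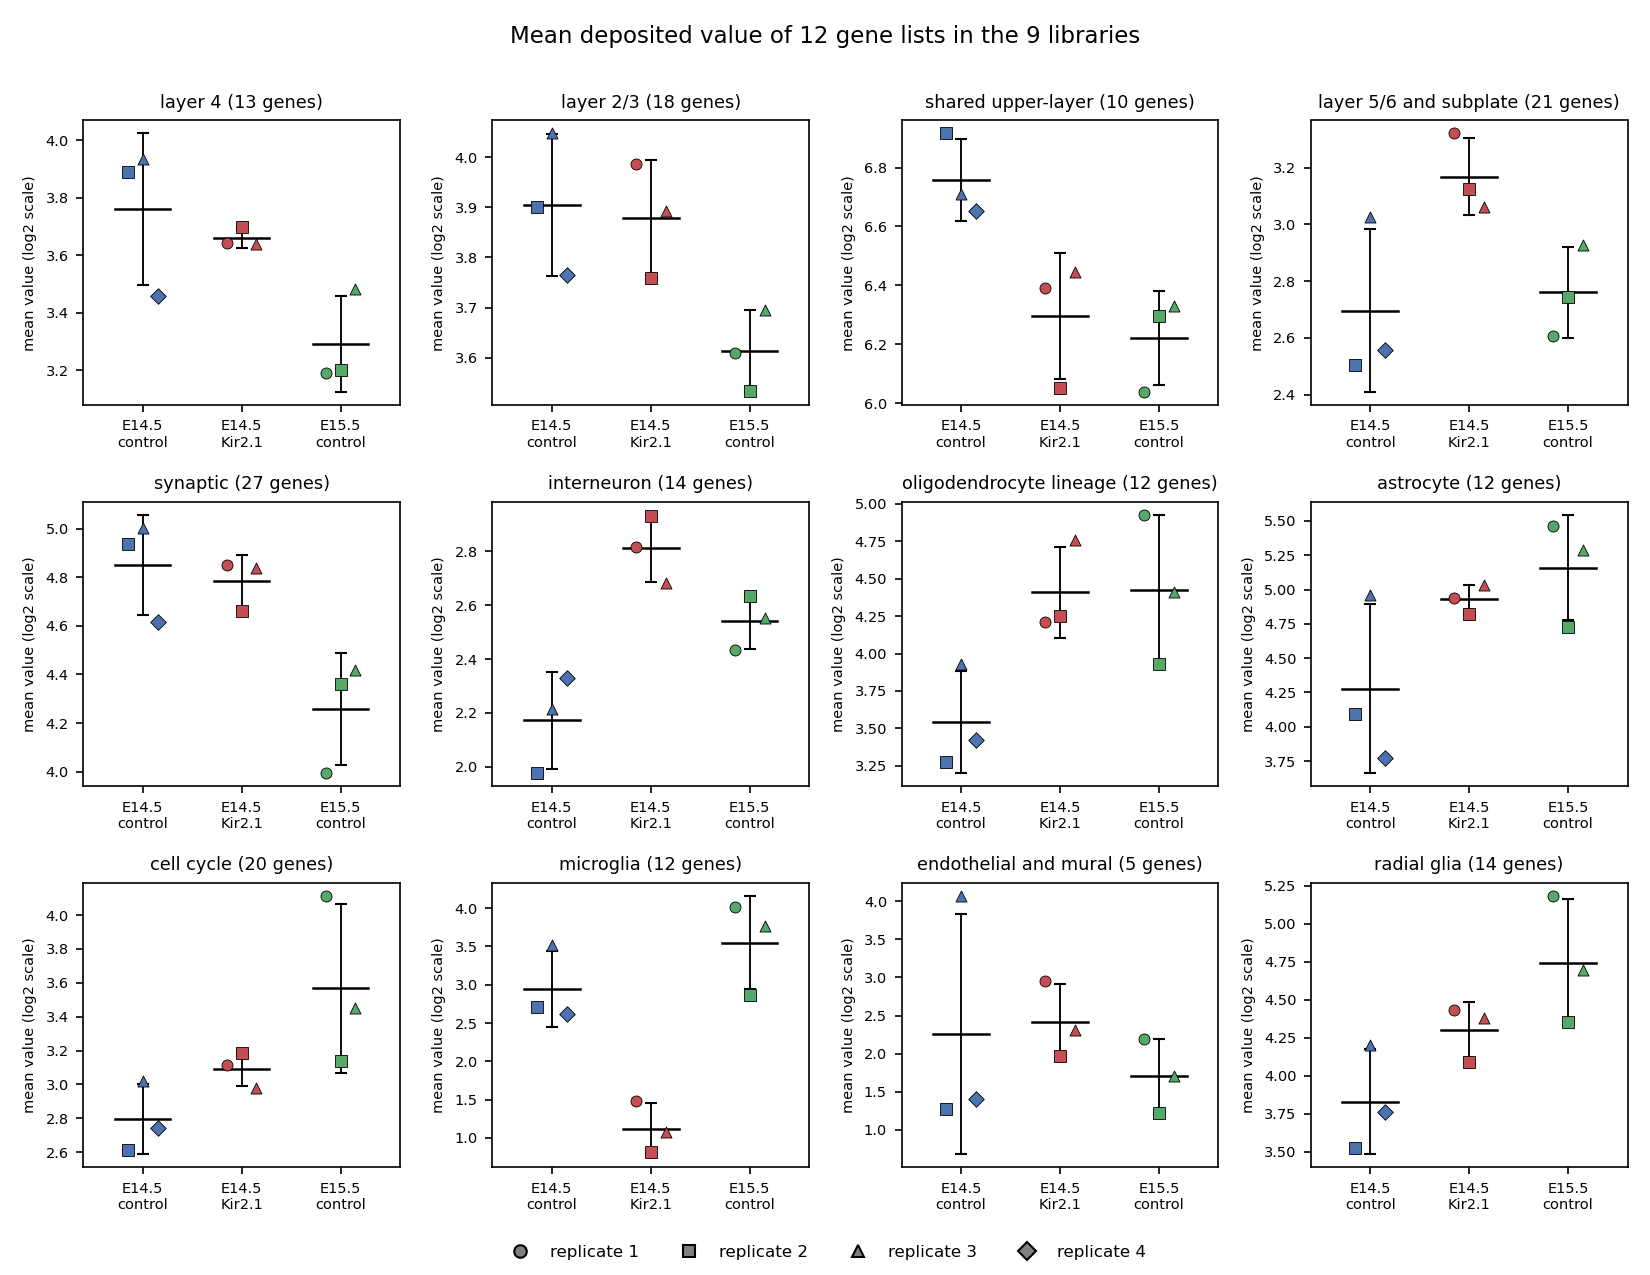
Mean deposited value (log2 scale) of 12 gene lists, 1 point per library, in the E14.5 control, Kir2.1 and E15.5 control groups; bars are group means with SD (n = 3) and the axes do not start at 0. The microglial list averages 0.81 to 1.48 in the Kir2.1 libraries and 2.62 to 4.02 in the other 6, and the endothelial and mural list is at 4.07 in E14.5 control replicate 3.

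The first comparison, Kir2.1 against the E14.5 control, asks how layer 4 and layer 2/3 genes differ between neurons electroporated on the same day. The groups differ in the channel and in the reporter (GFP or mCherry), and the 2 cannot be told apart. Membrane potential and birth date were not measured in these data. Microglial genes were far lower in the Kir2.1 libraries, with P2ry12, a purinergic receptor of microglia, at 53.14 ± 52.6 normalised reads against 729 ± 350 in the E14.5 control (13.7-fold). Genes shared by upper-layer neurons were lower, with a median difference of -0.51. Genes of oligodendrocyte lineage cells (median 0.91), interneurons (0.66), astrocytes (0.55) and deep-layer neurons (0.46) were higher as lists. With an estimated correlation each of these 6 list calls was lost (adjusted p from 0.175 to 0.249). With fry only the interneuron list passed (adjusted p = 0.028). The layer 4 and layer 2/3 lists passed no test with all 9 libraries. Kcnj2 itself, at chromosome 11, 111066164 to 111076821 (mm10, plus strand), had 291, 165.4 and 121.6 normalised reads in the Kir2.1 libraries against 109.6, 108.7 and 84.82 in the E14.5 control (1.91-fold). Every Kir2.1 library lay above every control, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 can give. The labels do not say from which species the plasmid's channel sequence was taken.

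Of 13 measured layer 4 genes, 7 lay above 0 and 6 below in Kir2.1 minus E14.5 control, and none passed when adjusted over the list alone. Their median was 0.06, their mean -0.10 and the direction of the camera test downwards (adjusted p = 0.632). Rorb, a nuclear receptor of layer 4 neurons (chromosome 19, 18930605 to 19111196, minus strand), had 13680 ± 3850 normalised reads in the Kir2.1 group and 25720 ± 13900 in the E14.5 control. The control libraries held 29690, 37160 and 10310 and the Kir2.1 libraries 9370, 14890 and 16780, so the groups overlapped (two-sided exact permutation p = 0.3). Kcnh5, a voltage-gated potassium channel, differed by -0.87 with SE 0.262, with an adjusted p over the list alone of 0.0688. Of 18 layer 2/3 genes, 8 lay above 0 and 10 below (median -0.20, camera adjusted p = 0.458; -0.33 without E14.5 control replicate 4 and -0.000565 without replicate 3). Adjusted over the list alone, 2 were higher and 1 lower, and over all genes none. Those higher were Calb1, which encodes calbindin (difference 1.26, 167.9 ± 80.1 against 33.32 ± 28 normalised reads), and Cdh13, a cadherin (0.64). The cells behind the Calb1 reads were not identified, and interneuron genes were also higher as a list (median 0.66). The lower one was Inhba, the activin A subunit (-0.75, 858.1 ± 156 against 1500 ± 185). Pou3f2, a transcription factor of upper-layer neurons (chromosome 4, 22482780 to 22488366), differed by -0.30 with SE 0.213.

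All 10 genes shared by upper-layer neurons lay below 0 in Kir2.1 minus E14.5 control (camera adjusted p = 6.17e-06), although none passed when adjusted over the list alone. The list had adjusted p = 0.217 with an estimated correlation. The homeobox gene Cux1 (chromosome 5, 136248135 to 136567490) differed by -0.59 with SE 0.225, and its relative Cux2 (chromosome 5, 121856366 to 122050102) by -0.69 with SE 0.268. Of 15 callosal genes 9 lay below 0 (median -0.22, camera adjusted p = 0.0446), and 1, Inhba, was lower when adjusted over the list alone. The callosal list had adjusted p = 0.242 with an estimated correlation. Its call also ended without E14.5 control replicate 2 (adjusted p = 0.0746), E14.5 control replicate 3 (0.149, with a median of 0.00432), Kir2.1 replicate 1 (0.0907) or Kir2.1 replicate 2 (0.139). Of 21 deep-layer and subplate genes 19 lay above 0 (camera adjusted p = 1.9e-07), and 4 were higher when adjusted over the list alone. The deep-layer list had adjusted p = 0.218 with an estimated correlation. The 4 were Fezf2 (2.7-fold) and Bcl11b (2.11-fold), transcription factors of subcerebral projection neurons, Etv1 (1.76-fold), a layer 5 transcription factor, and Ctgf, a subplate marker (294.3 ± 265 against 53 ± 70.8 normalised reads, with overlapping groups).

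All 14 interneuron genes lay above 0 in Kir2.1 minus E14.5 control (camera adjusted p = 1.15e-08), 7 of them higher when adjusted over the list alone. The list had adjusted p = 0.175 with an estimated correlation. Dlx2, a homeobox gene of interneuron precursors, was at 58.61 ± 26.9 against 11.27 ± 6.09 normalised reads, and Gad1, a GABA-synthesising enzyme, was 2.02-fold higher. All 12 oligodendrocyte lineage genes lay above 0 (camera adjusted p = 2.49e-11), 10 of them higher when adjusted over the list alone, among them Sox10 (2.8-fold) and Olig1 (1.8-fold), transcription factors of that lineage, and Cspg4 (2.5-fold). The oligodendrocyte list had adjusted p = 0.217 with an estimated correlation. All 12 astrocyte genes lay above 0 (camera adjusted p = 4.42e-06; with an estimated correlation, adjusted p = 0.249), none of them past the list-alone adjustment, and astrocyte genes were lowest in E14.5 control replicates 2 and 4, the libraries lowest on the first principal component. Radial glia genes (median 0.40, camera adjusted p = 0.000118, adjusted p = 0.306 with an estimated correlation) and cell cycle genes (0.30, 0.00385, adjusted p = 0.61 with an estimated correlation) were also higher as lists; the cell cycle call ended without E14.5 control replicate 2 (0.18, adjusted p = 0.0638). The astrocyte median was 0.85 without E14.5 control replicate 3, the library rich in blood and meningeal genes, and 0.32 without replicate 4, and the cell cycle median 0.47 without replicate 3. All 12 microglial genes were lower when adjusted over the list alone (median -1.88, camera adjusted p = 1.91e-27), and C1qb, a complement component, was 13.9-fold lower. The microglial list had adjusted p = 0.182 with an estimated correlation.

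Genes of Wnt and beta-catenin signalling were higher as a list in Kir2.1 than in the E14.5 control (median 0.23, camera adjusted p = 0.00152, adjusted p = 0.329 with an estimated correlation). 1 of them, the transcription factor Tcf7l2 (2.64-fold), passed when adjusted over the list alone. The cells behind the Tcf7l2 reads were not identified, and oligodendrocyte lineage genes were also higher in this comparison (median 0.91). Sodium and calcium channel genes were lower as a list (median -0.09, camera adjusted p = 0.0403, adjusted p = 0.507 with an estimated correlation), and Cacna1i, a T-type calcium channel, was the 1 member past the list-alone adjustment (-0.77). That list call ended without E14.5 control replicate 3 (adjusted p = 0.24), Kir2.1 replicate 2 (0.0661) or Kir2.1 replicate 3 (0.0804), and its median was -0.14 without E14.5 control replicate 2. The Wnt median was 0.36 without E14.5 control replicate 3. Slc17a6, a vesicular glutamate transporter, was at 1584 ± 201 normalised reads against 3576 ± 1400 and passed within the synaptic list alone (adjusted p = 0.0133), a list that did not pass as a whole (median -0.09, camera adjusted p = 0.317; -0.18 and 0.00968 without E14.5 control replicate 4, and a median of 0.0124 without replicate 2). Rgs2, a regulator of G-protein signalling counted among the late activity-response genes, was 2.55-fold lower (adjusted p over the list alone = 0.00273). Adjusted over all 12571 genes, limma called 0 genes in Kir2.1 minus E14.5 control (smallest adjusted p = 0.0928), and limma-voom on the recovered reads called 0. At an unadjusted p under 0.05 there were 628 higher and 360 lower genes, where chance alone gives 629 in both directions together. The groups did not overlap in 12.3% of genes, where chance gives 10%. Without E14.5 control replicate 3, 61 genes were called higher and 11 lower, and without E15.5 control replicate 2, which enters through the pooled spread, 12 were called lower. With the replicate number as a block, 37 were called lower and 0 higher. The layer 4 median was -0.06 without E14.5 control replicate 2, -0.01 without replicate 3, -0.21 without Kir2.1 replicate 2, and 0.08 without E14.5 control replicate 4, where the list passed downwards (adjusted p = 0.0418, mean difference -0.252) despite that median.

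**Figure D2:**
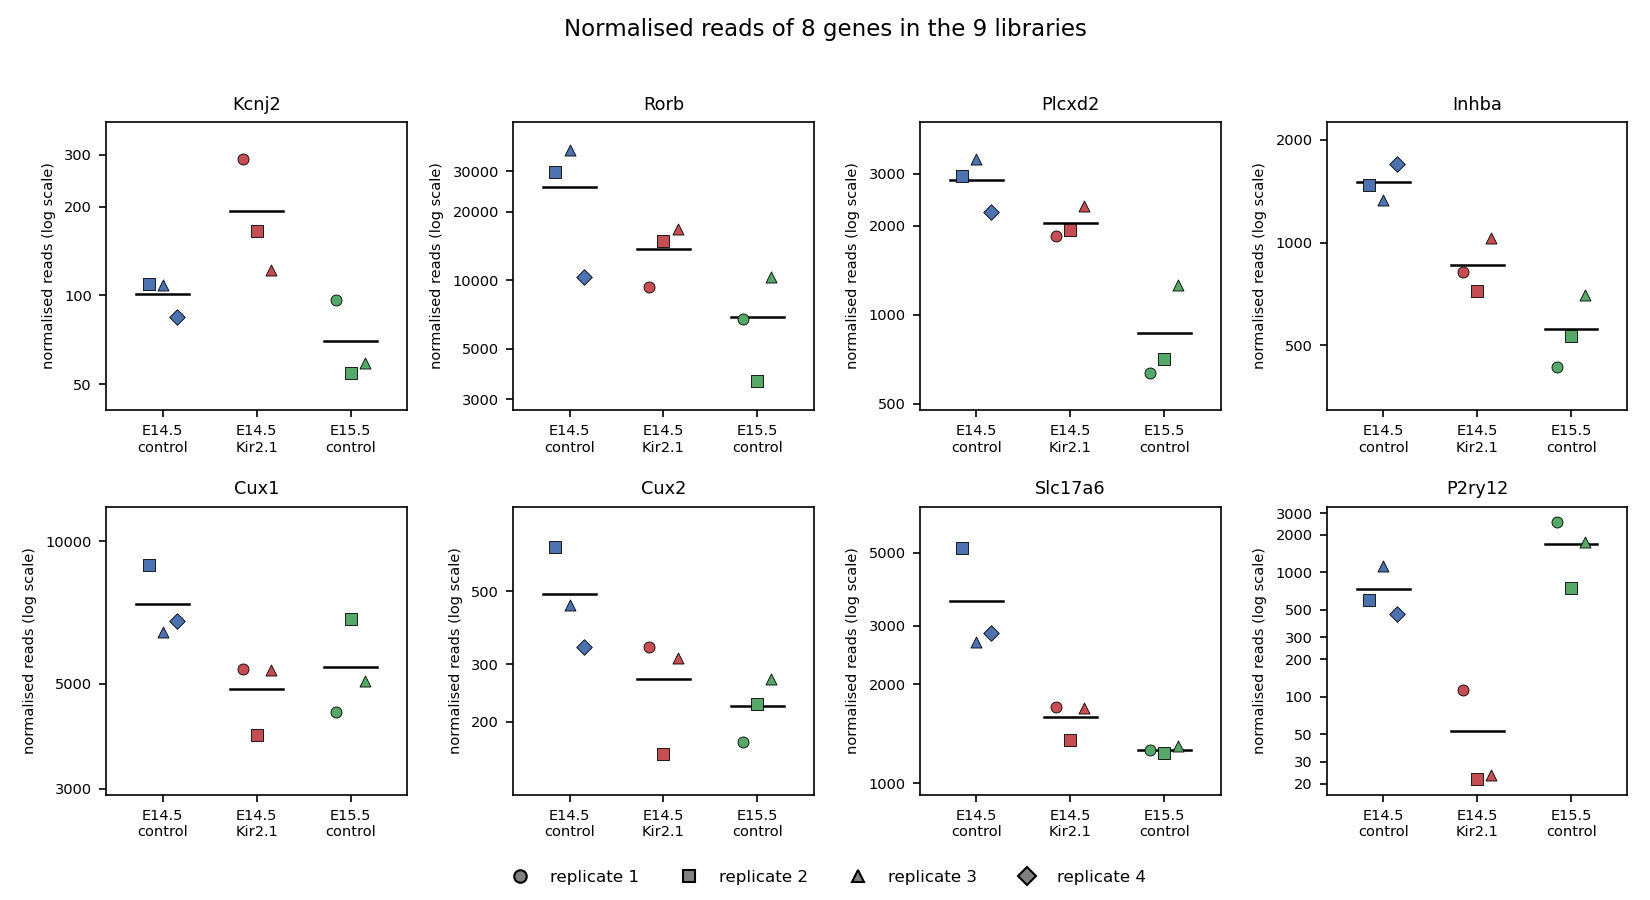
Normalised reads (log axis) of 8 genes in the E14.5 control, Kir2.1 and E15.5 control groups, 1 point per library, with lines at the group means (n = 3). Kcnj2 lies between 121.6 and 291 in the Kir2.1 libraries and at or below 109.6 in the other 6, and P2ry12 between 21.86 and 113.8 in the Kir2.1 libraries and at or above 460.3 in the others.

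The second comparison set neurons labelled at E15.5, a day on which layer 2/3 neurons are being born, against those labelled at E14.5, both with the reporter alone. Glial, radial glia and cell cycle genes were higher as lists in the E15.5 control, and synaptic, ion channel and upper-layer genes lower. With an estimated correlation every such call was lost (adjusted p from 0.201 to 0.499). With fry only the sodium and calcium channel list among them passed (adjusted p = 0.028). Fabp7, a fatty acid binding protein in the radial glia list, was at 24880 ± 2370 normalised reads against 10550 ± 3270 (2.36-fold). Syt1, a synaptic vesicle calcium sensor, was at 3156 ± 793 against 7069 ± 1400, 2.24-fold lower. Rorb was at 6892 ± 3350 against 25720 ± 13900, 3.73-fold lower, with every E15.5 control library below every E14.5 control (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give).

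Of 13 layer 4 genes 9 lay below 0 in E15.5 minus E14.5 control (median -0.36, camera adjusted p = 0.00555), and 4 were lower when adjusted over the list alone. The layer 4 list had adjusted p = 0.259 with an estimated correlation. The 4 were Rorb, Plcxd2 (3.28-fold, chromosome 16, 45959263 to 46010218), Kcnh5 (3.21-fold) and Zmat4 (4.3-fold). Of 18 layer 2/3 genes 10 lay below 0 and 8 above (median -0.08, camera adjusted p = 0.00832), and 7 were lower and none higher when adjusted over the list alone. The layer 2/3 list had adjusted p = 0.217 with an estimated correlation. Among the 7, Inhba (chromosome 13, 16011851 to 16031621) was 2.7-fold lower, Mdga1, an adhesion protein of superficial neurons, 2.6-fold lower, Pou3f1 1.82-fold lower and Kitl 2.64-fold lower. Pou3f2 was at 6581 ± 1330 against 6462 ± 1360. Of the 10 genes shared by upper-layer neurons 9 lay below 0 (median -0.53, camera adjusted p = 3e-05), 6 of them lower when adjusted over the list alone, Foxp1 by 2.37-fold and Cux2 by 2.2-fold. That list had adjusted p = 0.218 with an estimated correlation. Of 15 callosal genes 11 lay below 0 (median -0.50, camera adjusted p = 0.000178, adjusted p = 0.182 with an estimated correlation), 7 of them lower when adjusted over the list alone, among them Cpne4 (2.71-fold) and the lipase gene Lpl (2.04-fold). Deep-layer genes did not pass as a list (median 0.05, camera adjusted p = 0.712), with Etv1 1.97-fold higher and Ntsr1, a layer 6 receptor, 2.01-fold lower, both past the list-alone adjustment.

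Of 27 synaptic genes 26 lay below 0 in E15.5 minus E14.5 control (median -0.63, camera adjusted p = 8.45e-12), 15 of them lower when adjusted over the list alone, and Slc17a6 (chromosome 7, 51622006 to 51671119) was 2.83-fold lower. The synaptic list had adjusted p = 0.218 with an estimated correlation. All 21 sodium and calcium channel genes lay below 0 (median -0.46, camera adjusted p = 4.41e-10, adjusted p = 0.201 with an estimated correlation), 10 of them lower when adjusted over the list alone. Cacna1i was 4.48-fold lower. Of 31 potassium channel genes 24 lay below 0 (median -0.37, camera adjusted p = 2.22e-05, adjusted p = 0.218 with an estimated correlation). Adjusted over the list alone, 7 were lower, with Kcnh1 by 4.02-fold and Kcnma1 by 3.44-fold, and 1 higher. Glutamate and GABA receptor genes (median -0.19, camera adjusted p = 0.0107, adjusted p = 0.392 with an estimated correlation) and late activity-response genes (-0.20, 0.0466, adjusted p = 0.329 with an estimated correlation) were lower as lists. Past the list-alone adjustment, 1 receptor gene was higher and 6 lower, Gabra4 by 2.15-fold, and 2 late activity-response genes were higher and 4 lower, Rgs2 by 2.73-fold. The receptor call ended without E14.5 control replicate 3 (adjusted p = 0.0939) or E15.5 control replicate 1 (0.0899), and its median was -0.31 without E15.5 control replicate 2 and -0.29 without replicate 3. The late activity-response call ended without E14.5 control replicate 2 (0.0985), 3 (0.142) or 4 (0.0586) or E15.5 control replicate 1 (0.129), and its median was -0.30 without E15.5 control replicate 3.

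Of 14 radial glia genes 13 lay above 0 in E15.5 minus E14.5 control (median 0.96, camera adjusted p = 3.45e-09), 10 of them higher when adjusted over the list alone, with the transcription factor Sox2 2.55-fold higher. The radial glia list had adjusted p = 0.217 with an estimated correlation. Its median was near that of the astrocyte list (0.98), and the cells behind its reads were not identified, so progenitors were not shown to be present. All 20 cell cycle genes lay above 0 (median 0.82, camera adjusted p = 1.24e-10, adjusted p = 0.222 with an estimated correlation), 12 of them higher when adjusted over the list alone, with the kinase gene Cdk1 2.55-fold higher. All 12 astrocyte genes lay above 0 (median 0.98, camera adjusted p = 1.45e-07, adjusted p = 0.218 with an estimated correlation), 8 past the list-alone adjustment, and Sox9 was 2.5-fold higher. All 12 oligodendrocyte lineage genes lay above 0 (median 1.01, camera adjusted p = 4.88e-08, adjusted p = 0.226 with an estimated correlation), 9 past the list-alone adjustment, with Olig2 2.93-fold higher. All 12 microglial genes lay above 0 (median 0.60, camera adjusted p = 0.000732, adjusted p = 0.499 with an estimated correlation), none past the list-alone adjustment. Interneuron genes (median 0.30, camera adjusted p = 0.00493, adjusted p = 0.218 with an estimated correlation) and Wnt genes (0.31, 0.00343, adjusted p = 0.363 with an estimated correlation) were higher as lists. The interneuron call ended without E15.5 control replicate 2 (adjusted p = 0.0632). The astrocyte median was 0.65 without E14.5 control replicate 4, and the microglial median 0.35 without that library and 0.31 without E15.5 control replicate 1. E15.5 control replicate 1 had the highest cell cycle mean of the 9 libraries (4.11, against 3.14 and 3.45 in the other E15.5 controls), and without it the cell cycle median was 0.52.

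Adjusted over all genes, limma called 0 genes in E15.5 minus E14.5 control (smallest adjusted p = 0.0548), and limma-voom called 0. At an unadjusted p under 0.05 there were 1044 higher and 848 lower genes where chance gives 629 in all, or 1267 higher and 644 lower with total-read scaling, and the groups did not overlap in 16.3% of genes where chance gives 10%. The calls turn on single libraries: 292 higher and 77 lower without E14.5 control replicate 3, 31 higher and 94 lower without E14.5 control replicate 4, and 1 lower without E15.5 control replicate 3. With the replicate number as a block, 36 genes were called higher and 97 lower. Without E14.5 control replicate 3 the layer 4 and layer 2/3 lists no longer passed (medians -0.13 and -0.12, adjusted p = 0.0945 and 0.0863), and their medians were -0.20 and -0.20 without E14.5 control replicate 2, -0.07 for layer 4 without E15.5 control replicate 1 and -0.13 for layer 2/3 without E15.5 control replicate 2.

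Both comparisons used the same E14.5 control libraries, and the differences were set against each other across genes, which are not independent replicates. Pearson's r between Kir2.1 minus E14.5 control and E15.5 minus E14.5 control was 0.601. Simulated unchanged groups, with a control group drawn anew and shared by both differences, gave a mean of 0.436 and a 95% range of -0.453 to 0.935. They drew every group from a single pooled spread. Limma's library weights, lower for a more variable library, were 0.405 to 0.654 in the E14.5 controls and 1.1 to 1.76 in Kir2.1. They were 0.609, 0.67 and 4.8 in the E15.5 controls. If the E14.5 controls vary more than simulated, the simulated covariance is too low, so the simulations cannot decide whether the 2 differences are related. The covariance was 0.0744 against a simulated mean of 0.0313, a difference of 0.0431, and 89 of 1000 simulations reached it. Without E14.5 control replicate 3 the covariance was 0.144. The 2 differences had the same sign in 70.8% of genes, against 65.5% simulated. At an unadjusted p under 0.05, 327 genes were higher in both, where independent lists give 52.2. The simulated unchanged groups gave a mean of 102 (95% range 0 to 806, 9 of 100 simulations as large). Lower in both were 151, where independent lists give 24.3 and the simulations 95.4 (0 to 837, 19 as large). The 3 controls cannot be parted into sets of 2, so part or all of the excess over these values may come from the shared controls.

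The third comparison set the Kir2.1 neurons against the E15.5 control, the later-labelled group, to ask how far the 2 kinds of neuron differ directly. Genes of microglia were lower in the Kir2.1 libraries, and members of the microglial list made up 10 of the 22 genes called. Other genes of immune cells, named below, were also among the 22. P2ry12 (chromosome 3, 59216272 to 59262871) was at 53.14 ± 52.6 normalised reads against 1677 ± 898, 31.6-fold lower. Synaptic, ion channel and deep-layer genes were higher as lists in Kir2.1, as were the layer 4 and layer 2/3 lists, and cell cycle and radial glia genes were lower. With an estimated correlation these list calls were lost too (adjusted p from 0.217 to 0.306). None of them passed with fry, where the microglial list did (adjusted p = 0.028). Kcnj2 was at 192.6 ± 87.9 against 69.93 ± 22.9, 2.75-fold higher, with every Kir2.1 library above every E15.5 control (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give).

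All 12 microglial genes were lower in Kir2.1 minus E15.5 control when adjusted over the list alone (median -2.52, camera adjusted p = 8.33e-36). The microglial list had adjusted p = 0.175 with an estimated correlation. Among the genes called by limma over all genes, C1qb (chromosome 4, 136880129 to 136886187) differed by -2.77 with SE 0.311 and an adjusted p of 0.00315, the same adjusted p as P2ry12 (-3.66, SE 0.41). Ctss, a lysosomal protease, was 22.3-fold lower and Tyrobp, an immune signalling adaptor, 25.5-fold lower. Fcer1g, Ly86, Fcrls and Laptm5, genes of immune cells of which Fcrls is in the microglial list, were 16.4-fold, 12.3-fold, 19.7-fold and 21.7-fold lower, each with an adjusted p of 0.00932.

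Of 13 layer 4 genes 12 lay above 0 in Kir2.1 minus E15.5 control (median 0.29, camera adjusted p = 0.00183), and 1, Plcxd2 (2.35-fold), was higher when adjusted over the list alone. The layer 4 list had adjusted p = 0.222 with an estimated correlation. Rorb was at 13680 ± 3850 against 6892 ± 3350, with overlapping groups (two-sided exact permutation p = 0.2). Of 18 layer 2/3 genes 14 lay above 0 (median 0.28, camera adjusted p = 0.0036), and 4 were higher when adjusted over the list alone. They were Calb1 (5.31-fold), Cdh13 (1.71-fold), Plxnd1, a semaphorin receptor (2.47-fold), and Kitl (2.06-fold, with overlapping groups). The cells behind the Calb1 reads were again not identified. The layer 2/3 list had adjusted p = 0.217 with an estimated correlation. Genes shared by upper-layer neurons did not pass as a list (median 0.14, camera adjusted p = 0.52). Callosal genes (median 0.20, camera adjusted p = 0.00517, adjusted p = 0.217 with an estimated correlation) and deep-layer genes (0.47, 2.05e-06, adjusted p = 0.226 with an estimated correlation) were higher as lists, with Cpne4 2.3-fold higher and past the callosal list-alone adjustment. Without E15.5 control replicate 1 the callosal median was 0.12 and the deep-layer median 0.29, and without E15.5 control replicate 2 the callosal median was 0.30.

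All 27 synaptic genes lay above 0 in Kir2.1 minus E15.5 control (median 0.58, camera adjusted p = 1.74e-13), 5 of them higher when adjusted over the list alone, with Syt1 2.08-fold and Cplx2 1.85-fold higher. The synaptic list had adjusted p = 0.217 with an estimated correlation. Potassium channel genes (median 0.28, camera adjusted p = 2.28e-05, adjusted p = 0.218 with an estimated correlation) were higher, and 4 passed when adjusted over the list alone, among them Kcnj2 itself and Kcnj9 (2.67-fold). Of 21 sodium and calcium channel genes 20 lay above 0 (median 0.36, camera adjusted p = 2.54e-08, adjusted p = 0.217 with an estimated correlation), and 1, Scn2b (2.74-fold), passed the list-alone adjustment. Receptor genes for glutamate and GABA (0.28, 2.22e-05, adjusted p = 0.218 with an estimated correlation) and axon guidance genes (0.15, 0.0189, adjusted p = 0.647 with an estimated correlation) were also higher as lists. Efna5, an ephrin ligand, was 3.77-fold higher and the 1 axon guidance gene past the list-alone adjustment. All 20 cell cycle genes lay below 0 (median -0.44, camera adjusted p = 1.66e-07, adjusted p = 0.306 with an estimated correlation), none past the list-alone adjustment. Of 14 radial glia genes 13 lay below 0 (median -0.39, camera adjusted p = 0.000118, adjusted p = 0.306 with an estimated correlation), and 1, Fabp7 (1.85-fold), passed it. Interneuron genes were higher (median 0.12, camera adjusted p = 0.0268, adjusted p = 0.263 with an estimated correlation), and astrocyte genes lower (-0.21, 0.0358, adjusted p = 0.644 with an estimated correlation). Oligodendrocyte lineage genes did not pass as a list (median -0.00227, camera adjusted p = 0.86), but were higher without E15.5 control replicate 1 (0.31, 0.0471). Without that library the cell cycle median was -0.19 and the radial glia median -0.21, and without E15.5 control replicate 2 they were -0.68 and -0.69. The interneuron call ended without Kir2.1 replicate 1 (adjusted p = 0.0509), Kir2.1 replicate 2 (0.121) or E15.5 control replicate 3 (0.0581). The astrocyte call ended without Kir2.1 replicate 1 (0.0506), Kir2.1 replicate 2 (0.0958), E15.5 control replicate 1 (0.286) or E15.5 control replicate 3 (0.121), with a median of -0.50 without E15.5 control replicate 2. The axon guidance call ended without Kir2.1 replicate 1 (0.0506), Kir2.1 replicate 3 (0.0519) or E15.5 control replicate 2 (0.726).

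Adjusted over all genes, limma called 22 genes lower and 0 higher in Kir2.1 minus E15.5 control, and limma-voom called 0 (smallest adjusted p = 0.0515). At an unadjusted p under 0.05 there were 591 higher and 419 lower genes, or 442 higher and 561 lower with total-read scaling, and the groups did not overlap in 18.1% of genes where chance gives 10%. The 22 fell to 2 without Kir2.1 replicate 2 or E15.5 control replicate 3, to 3 without E15.5 control replicate 1, and to 4 without Kir2.1 replicate 3 or without both E14.5 control replicate 2 and E15.5 control replicate 1, and rose to 42 without E15.5 control replicate 2 and to 34 without E14.5 control replicate 3. With the replicate number as a block, 32 genes were called higher and 60 lower.

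**Figure D3:**
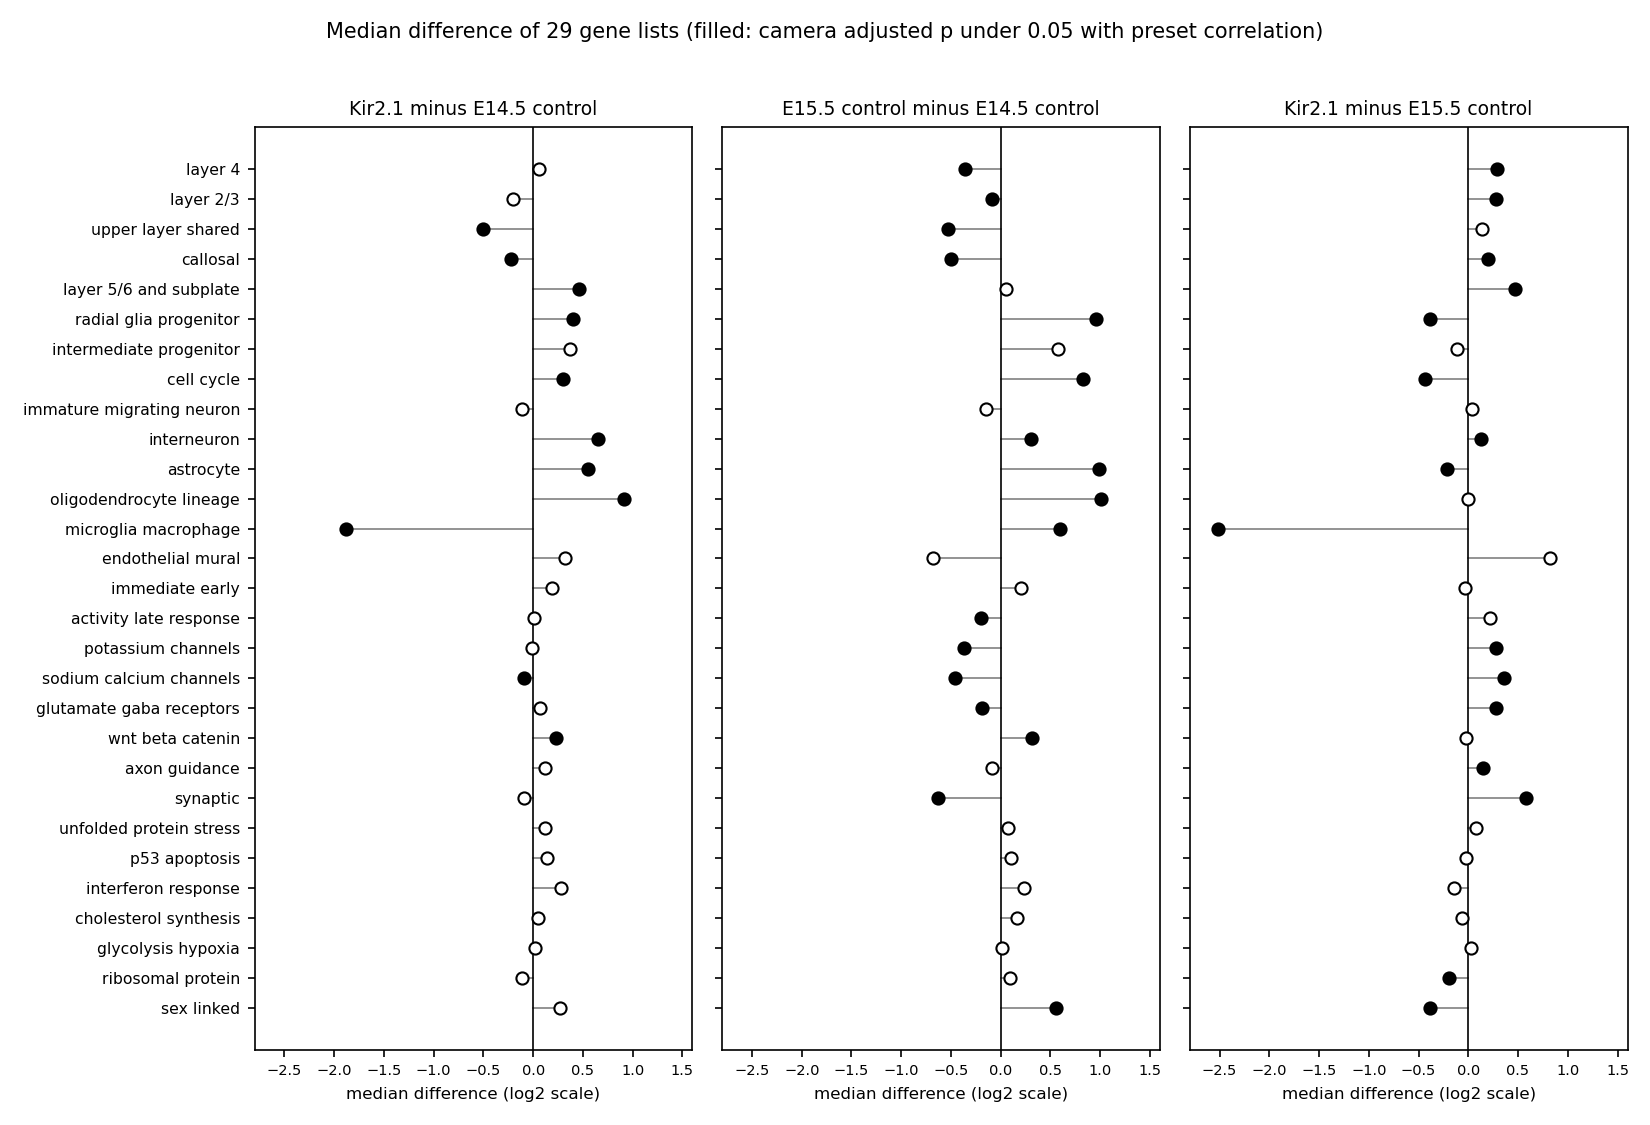
Median difference (log2 scale) of 29 gene lists in the 3 comparisons; filled points have a camera adjusted p under 0.05 with the preset correlation. The microglial list is lowest in both Kir2.1 panels (-1.88 and -2.52), and 0 of the 29 lists in each panel pass with an estimated correlation.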

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

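The alternatives with log2(CPM+1), voom, total-read scaling, quantile normalization, library weights, the 2 doubted libraries left out (E14.5 control replicate 2 and E15.5 control replicate 1) and thinned reads were chosen after seeing the data; the cause of the changes below was not tested except where stated. Calls in Kir2.1 against E14.5 control were 0 higher and 0 lower, and the lower ones became 7 with log2(CPM+0.1), 5 with log2(CPM+1), 5 with quantile normalization and 8 with library weights. Leaving out 1 library gave 0 to 61 higher and 0 to 12 lower. In E15.5 against E14.5 control, 0 higher and 0 lower became 10 and 19 with log2(CPM+5), 18 and 29 with the stricter filter, which tests 10832 genes, 12 and 22 with quantile normalization, and 62 and 39 with library weights. Leaving out 1 library gave 0 to 292 higher and 0 to 94 lower. In Kir2.1 against E15.5 control, 0 higher and 22 lower became 4 and 41 with 6 libraries only and 67 and 106 with library weights; 1 was higher with log2(CPM+1), the stricter filter or quantile normalization; 0 were lower with voom under either scaling and 4 with both doubted libraries left out. Leaving out 1 library gave 0 to 2 higher and 2 to 42 lower. Voom with total reads shifted the median of all genes by 0.10 in E15.5 against E14.5 control. No label says what the replicate numbers stand for. Of 7 same-numbered pairs 6 had deviations correlated over 0.1 (all 7 from -0.025 to 0.24). Pairs with different numbers ran from -0.49 to 0.34, and most of them lay below 0.1. Not every library correlated best with its own number, since E14.5 control replicate 3 reached 0.34 with E15.5 control replicate 1. Whether the numbers pair the libraries therefore stays open. With the replicate block 0 higher and 37 lower genes, 10 of them microglial, were called in Kir2.1 against E14.5 control, 36 and 97 in E15.5 against E14.5 control, and 32 and 60 in Kir2.1 against E15.5 control. Of the list calls 44 became 43, with 7 ended and 6 new.

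The layer 4 median in Kir2.1 against E14.5 control, 0.06, was -0.24 with the stricter filter (adjusted p = 0.231) and -0.0616 with both doubted libraries left out, and ranged from -0.207 to 0.0751 when 1 library was left out; the layer 2/3 median ranged from -0.328 to -0.000565. In E15.5 against E14.5 control the medians were -0.36 for layer 4 and -0.0848 for layer 2/3, and the adjusted p values were 0.12 and 0.0794 for fry and 0.259 and 0.217 with an estimated correlation; leaving out 1 library gave medians of -0.368 to -0.0731 and -0.195 to -0.0848, with adjusted p up to 0.0945 and 0.0863. In Kir2.1 against E15.5 control the medians, 0.29 and 0.28, were 0.21 to 0.313 and 0.237 to 0.345 when 1 library was left out, and the adjusted p values were 0.15 and 0.107 for fry and 0.222 and 0.217 with an estimated correlation. Of the 87 list medians 26 changed sign when 1 library was left out, 1 of them called: callosal in Kir2.1 against E14.5 control, 0.00432 without E14.5 control replicate 3 (range -0.313 to 0.00432). Among the others, oligodendrocyte lineage in Kir2.1 against E15.5 control was 0.307 without E15.5 control replicate 1 (range -0.305 to 0.307). Lists not called in the main fit of all 9 libraries but called without 1 library include endothelial genes in E15.5 against E14.5 control (-1.24, adjusted p = 0.0175, without E14.5 control replicate 2). The covariance between the first 2 comparisons, 0.0744 where simulated unchanged groups gave a mean of 0.0313 and reached it in a share of 0.0899, was 0.0666 to 0.144 when 1 library was left out, and groups simulated anew reached it in shares of 0.0519 to 0.271. The planned count-model test, its size factors (already the authors' own) and no filter were not run. The deposited unit is a log2 value, already filtered. The whole reads recovered from it would have allowed a count model, but were tested with limma-voom only. The choice matters, since voom called 0 genes in Kir2.1 against E15.5 control where the main fit called 22. Depth limits the weakly expressed genes, whose changes the deposited scale understates.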

Other observations

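Several gene groups did not pass as lists with all 9 libraries. Intermediate progenitor genes had a median of 0.37 in Kir2.1 minus E14.5 control (camera adjusted p = 0.133), 0.57 in E15.5 minus E14.5 control (0.0902; 0.73 and 0.0299 without E15.5 control replicate 2, and a median of 0.31 without replicate 1) and -0.12 in Kir2.1 minus E15.5 control (0.68; the median was 0.22 without E15.5 control replicate 1). Immature migrating neuron genes stood at -0.11 (0.691), -0.15 (0.691) and 0.04 (0.86), although Reln, the extracellular protein of Cajal-Retzius cells, was 2.89-fold higher in Kir2.1 than in the E14.5 control and passed within its list alone (adjusted p = 0.0254). Endothelial and mural genes stood at 0.32 (0.835), -0.68 (0.234) and 0.82 (0.0785), and without E14.5 control replicate 3 they were 0.79 (0.00147), 0.59 and 0.82 (0.00181). The first had a median of -0.409 without E14.5 control replicate 2. The second was also -1.24 (0.0175) without E14.5 control replicate 2 and -1.04 (0.0418) without replicate 4, and the third passed without Kir2.1 replicate 2 (0.0231) or E15.5 control replicate 1 (0.0107). Immediate-early genes stood at 0.19 (0.278), 0.20 (0.548) and -0.03 (0.831), with ranges of 0.0453 to 0.476, 0.0669 to 0.412 and -0.231 to 0.169 when 1 library was left out, and unfolded protein and stress genes at 0.12 (0.354), 0.07 (0.86; 1 member higher when adjusted over the list alone) and 0.07 (0.548). The p53 and apoptosis list stood at 0.14 (0.835), 0.10 (0.994) and -0.02 (0.85), interferon response at 0.28 (0.723), 0.23 (0.548) and -0.15 (0.658), cholesterol synthesis at 0.05 (0.167), 0.16 (0.13; 1 member higher when adjusted over the list alone) and -0.06 (0.691), and glycolysis and hypoxia at 0.02 (0.98), 0.01 (0.712) and 0.03 (0.698). The first interferon median was -0.0277 without E14.5 control replicate 2. Cholesterol synthesis passed in the first comparison without E14.5 control replicate 2 (0.0302) or 4 (0.0153) or Kir2.1 replicate 3 (0.0415), although its median there ran from -0.162 to 0.163 when 1 library was left out, and in the second without E14.5 control replicate 2 (0.0267) or 4 (0.0216) or E15.5 control replicate 1 (0.0246). Median, mean and test differed in sign for glycolysis in the first 2 comparisons, and for immediate-early and p53 genes in the third.

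Ribosomal protein genes were lower as a list in Kir2.1 minus E15.5 control (median -0.20, camera adjusted p = 0.00437, adjusted p = 0.74 with an estimated correlation), a call that ended without Kir2.1 replicate 2 (0.327) or E15.5 control replicate 2 (0.561), with -0.12 (0.133; -0.20 and 0.00343 without E14.5 control replicate 2, -0.235 and 0.00131 without Kir2.1 replicate 3) in Kir2.1 minus E14.5 control and 0.09 (0.342; 0.21 and 0.0215 without E14.5 control replicate 4, 0.22 and 0.00517 without E15.5 control replicate 1) in E15.5 minus E14.5 control. In the third comparison the ribosomal median was also -0.33 without Kir2.1 replicate 3 and -0.32 without E15.5 control replicate 1. The sex-linked list joins Xist with genes of the Y chromosome, which sex moves in opposite ways, so its direction has no single meaning. As a list these genes were higher in E15.5 minus E14.5 control (0.55, 0.0444, adjusted p = 0.329 with an estimated correlation) and lower in Kir2.1 minus E15.5 control (-0.39, 0.0303, adjusted p = 0.306 with an estimated correlation), with 0.27 (0.586) in Kir2.1 minus E14.5 control. The first of these calls ended when any of 6 single libraries was left out (adjusted p from 0.0506 to 0.176), and the second without Kir2.1 replicate 2 (0.124), E15.5 control replicate 1 (0.168) or E15.5 control replicate 2 (0.0516). Xist, the X-inactivation transcript, was at 1034 ± 764 normalised reads in the E14.5 control, 250.7 ± 140 in Kir2.1 and 315.1 ± 117 in the E15.5 control, and Ddx3y, on the Y chromosome, at 329.6 ± 107, 501.1 ± 63.2 and 866.8 ± 285. The mix of sexes may therefore differ between the groups in every comparison, which was not tested. In Kir2.1 minus E14.5 control, late activity-response genes stood at 0.01 (0.635; the mean was -0.07), potassium channels at -0.01 (0.381; -0.05 and 0.0154 without E14.5 control replicate 4), glutamate and GABA receptors at 0.07 (0.458) and axon guidance at 0.12 (0.0859; 0.25 and 0.015 without E14.5 control replicate 3, 0.16 and 0.0474 without Kir2.1 replicate 2, and a median of 0.0371 without E14.5 control replicate 4). Axon guidance stood at -0.08 (0.68) in E15.5 minus E14.5 control, with 2 members higher and 4 lower when adjusted over the list alone. In Kir2.1 minus E15.5 control, late activity-response genes stood at 0.21 (0.0602; adjusted p from 0.0267 to 0.0488 without Kir2.1 replicate 2 or 3 or E15.5 control replicate 2 or 3) and Wnt genes at -0.02 (0.712).

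The patterns weighed next were found in these data. The tests of microglial proportions, of neuron and upper-layer shares, and of depth for microglia were chosen after the result was seen, and those of shares were revised after their first results: the endothelial list was added to the E15.5 test, where 3 lists alone had shown no difference, the condition that a difference hold without each library in turn was then added to all 3, and the upper-layer test was last made again on 6 types without microglia, whose fall had been seen, which turned its outcome from argued against to open. The first pattern is the lower level of microglial genes in the Kir2.1 libraries. Over the 12 genes the log2 fold of Kir2.1 over E15.5 control had an interquartile range of 0.408 (median -4.40, from -4.98 to -2.04), which is consistent with RNA of microglia present in different shares; the most abundant in the E15.5 control, Cx3cr1, named after its values were seen, was at 85.61 against 1687 normalised reads. A higher share of neurons, lowering all other types alike, is argued against by the microglial minus oligodendrocyte difference of -2.42 (95% interval -3.08 to -1.75). Without each library in turn the difference itself ran from -2.69 to -2.21, and 0 of the 9 intervals held 0. In log2 folds of normalised reads the list medians were -4.4 for microglia and -0.00451 for the oligodendrocyte lineage. Depth is argued against by the median of -2.35 with reads thinned. No share of cells was measured. If the share of microglia did differ, whether the plasmid, the collection of the neurons or the litter set it stays open and was not tested.

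The second pattern is the higher glial, radial glia and cell cycle genes and lower synaptic genes in the E15.5 control. E15.5 control replicate 1 alone is argued against by medians of 0.522 for cell cycle and -0.45 for synaptic genes without it, and depth by 0.788 and -0.602 with reads thinned. A lower share of neurons that raises all other types alike cannot be told apart from a change in the cells: the astrocyte minus endothelial difference was 1.43 (95% interval 0.134 to 2.72; 0.862 without E14.5 control replicate 3), but the interval reached 0 without 4 of the 6 libraries compared, and was wider in those 4. The astrocyte minus endothelial difference is also on the deposited scale, which flattens at low reads, so equal folds need not give equal values. The later birth date of the labelled neurons stays open.

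The third pattern is the higher deep-layer and interneuron genes and lower shared upper-layer genes in Kir2.1 than in the E14.5 control. E14.5 control replicate 2 alone is argued against by medians of 0.378, 0.523 and -0.449 without it, and depth by 0.419, 0.61 and -0.506 with reads thinned. That does not address the split of the controls. The deep-layer mean was 2.505 and 2.559 in E14.5 control replicates 2 and 4, 3.026 in replicate 3 and 3.06 to 3.321 in Kir2.1. Its median was 0.627 without replicate 3 and 0.328 without replicate 4. For the interneuron and shared upper-layer lists replicate 3 (2.214 and 6.709) lay between replicates 2 and 4. A lower share of upper-layer neurons that raises all other types alike, microglia among them, is argued against by the fall of the microglial list (median -1.88, all 12 genes below 0). The interneuron minus microglial difference was 2.46 (95% interval 1.36 to 3.56). Without each library in turn the difference itself ran from 2.2 to 2.7, and 0 of the 9 intervals held 0. The 2 lists had already been seen to move in opposite ways, so that difference restates the pattern and is no added test. With microglia set apart, as a fall of their own, a lower share of upper-layer neurons cannot be told apart from a change in the cells. Of 15 pairs of 6 lists, 1 had an interval that left out 0, the oligodendrocyte minus radial glia difference of 0.394 (95% interval 0.023 to 0.764). That interval reached 0 without 5 of the 6 libraries compared. It was wider in each of these except without Kir2.1 replicate 3, where the difference itself was smaller (0.256, -0.063 to 0.574). These differences between lists are on the deposited scale, which flattens at low reads, so equal folds need not give equal values. The interneuron and oligodendrocyte medians were 0.66 and 0.91 on that scale, and 0.993 and 1.03 as log2 folds of normalised reads. A change in the interneuron and deep-layer share alone, and an effect of the channel, stay open.

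There are 10 splits of 6 libraries into 3 and 3, too few for a share under 0.05. For genes called in Kir2.1 against E14.5 control the real split gave 0 and the highest other 0, so all 10 splits gave as many; in E15.5 against E14.5 control the real split gave 0 and the highest other 192, again with 10 as large; in Kir2.1 against E15.5 control the real split gave 22 and the highest other 0, with 1 as large. For lists, adjusted within a comparison, the real and highest other splits gave 9 and 10 (5 as large), 17 and 13 (1 as large) and 16 and 14 (1 as large). The split with 192 genes put E14.5 control replicates 2 and 4 and E15.5 control replicate 2 against the rest, and why was not tested.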
